A study of Mus musculus with 8 samples.

How the data were processed

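DNA methylation was measured by bisulfite sequencing in 8 samples of the 4T1 model, a transplantable mammary carcinoma cell line from BALB/c mice that spreads to the lung. Per the labels, the samples were 2 primary tumors marked MFP, 3 lung metastases marked MFP and 3 lung metastases marked TVI. The abbreviations MFP and TVI are kept as the labels give them. Per the labels' protocols, DNA was extracted with the ZR-Duet DNA/RNA miniprep and converted with the EZ-DNA Methylation Gold kit, which turns unmethylated cytosine into uracil and leaves methylated cytosine in place. The submitters' processing notes name Trimmomatic, Bismark and mm10, with no version or setting. How the covered positions were selected, and any filter on coverage, are not given in the sources used here.

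The authors deposited a single table of beta values, the fraction of calls at a position that were methylated, from 0 to 1, per the file headers. It held 136069 positions, here called sites, on 20 chromosomes, with no missing value and no position listed more than once. No column held values of an unlabelled sample, and no pair of samples had identical values. The table gave no read counts or coverage, so the depth behind each value is unknown and no interval or detection floor was computed. Precision could therefore be judged only from the spread between samples of a group. Nothing in the labels says whether samples of a group came from separate animals, so p-values measure the spread between these samples, which may be technical.

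The genome build of the coordinates was not settled. Of the 3166 sites on chromosome 7, 557 lay beyond the last gene end on that chromosome in the gene table of GRCm38.p6 (position 145324059), the highest at position 152129719. Among 26390 sites with a mean fraction under 10%, 8.61% lay within 500 bp of a gene end in that table, against 2.60% to 5.19% after the positions were shifted in 20 ways. The coordinates were therefore not treated as mm10 (GRCm38), and no gene, exon, promoter or other annotation was assigned to any site. Analyses of promoters, gene lists, cell type marker lists and genomic context, planned before the data were examined, need a reference of the same build and are not reported here. All positions below are given as deposited.

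For each site with any variation (135914 of 136069), fractions were fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 8 samples, so that the groups shared 1 estimate of the spread. Moderated tests used a variance trend, were two-sided and were adjusted by the Benjamini-Hochberg method over all sites, with a threshold of 0.05. The comparisons were the mean of both metastasis groups against the primary tumors, each metastasis group against the primary tumors, and TVI against MFP metastases. Differences are in percentage points of methylation. Per-sample means, medians and shares of sites at most 20%, at least 80% and from 35% to 65% were compared with two-sided exact permutation tests. Those 20 tests formed 1 family for the adjusted p.

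Because genes could not be placed, regions were added after the data were examined. Neighboring sites at most 500 bp apart were joined, and the mean fraction of each region with at least 3 sites was tested with the same model. This gave 3083 regions holding 135731 sites, with a median of 31 sites and a median length of 1935 bp. A further 233 groups of sites below the minimum were left out. The number of other sites within 250 bp was used as the local site density, with classes chosen after an exploratory look at the values.

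Named items followed a rule written before the data were examined, for promoters or, failing a placement on genes, for positions. For all metastases against primary tumors these were the 10 largest rises and the 10 largest falls that passed the threshold, with every metastasis on the same side of both tumors. For the other comparisons the 5 largest rises and 5 largest falls were taken. The same rule was then applied to regions.

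The procedure was tested on simulated data with the mean of each item over all 8 samples and its fitted spread. Each comparison had a single draw, with 50 items changed at each size and 200 in all. Items were drawn independently, without the correlation between neighboring sites. The real TVI against MFP comparison called 23001 sites, so its adjusted threshold was less strict than in the simulation, and the recovered shares do not describe it closely. For MFP metastases against primary tumors, site changes of 10, 20, 30 and 40 points were recovered in 8%, 64%, 90% and 100% of cases, and 7.09% of calls were false, over 135913 sites. For TVI against MFP metastases the shares were 10%, 72%, 90% and 100%, with 5.56% false, over 135911 sites. For all metastases against primary tumors they were 6%, 52%, 98% and 100%, with 6.57% false. Over the 3083 regions, the changes were of 1, 2, 4 and 8 points. They were recovered in 8%, 26%, 86% and 100% of cases for MFP metastases against primary tumors (6.78% false). The shares were 4%, 44%, 92% and 100% for TVI against MFP metastases (3.23% false), and 2%, 38%, 80% and 100% for all metastases against primary tumors (3.51% false). The sizes for regions were lowered after a first simulation recovered every change.

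Alternatives were the log2 odds of the fraction limited to 1% and 99%, quantile normalization across samples, other variance models, the replicate number as a block, the samples of a comparison alone, a minimum difference or range of 10 points, and leaving out each sample. Quantile normalization gives every sample the same distribution, so it removes a net gain of a group whatever its cause. Regions were also built with gaps of 200 and 1000 bp and with at least 1 and 5 sites, and the metastases were fitted as 1 group, all added after the data were examined. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and data.table (version 1.17.8), and plots were drawn with matplotlib 3.10.9.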

Results

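Methylation was compared at 136069 sites in 2 primary tumors (MFP), 3 lung metastases of the MFP group and 3 lung metastases of the TVI group, to ask how lung metastases of the 4T1 model differ from primary tumors. Lung metastases carried slightly more methylation than primary tumors. Mean methylation was 66.7% ± 0.223 (SD, n = 2) in primary tumors, 67.4% ± 0.0396 (SD, n = 3) in MFP metastases and 68.6% ± 0.0921 (SD, n = 3) in TVI metastases. The share of sites at 80% or more was 60.8% ± 0.474, 62.0% ± 0.0660 and 63.5% ± 0.0289 in the same groups. The share of sites at 20% or less was 22.9% ± 0.0805, 22.6% ± 0.0367 and 21.9% ± 0.194. All 6 metastases lay above both tumors in mean methylation, a difference of 1.29 points (two-sided exact permutation p = 0.0714, the smallest that 28 splits allow). The exact p was 0.2 for each metastasis group against the tumors and 0.1 for TVI against MFP metastases, also the smallest possible, and the adjusted p was 0.2 throughout the 20 tests. Sequencing depth is unknown, since the values are fractions without counts.

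**Figure D1:**
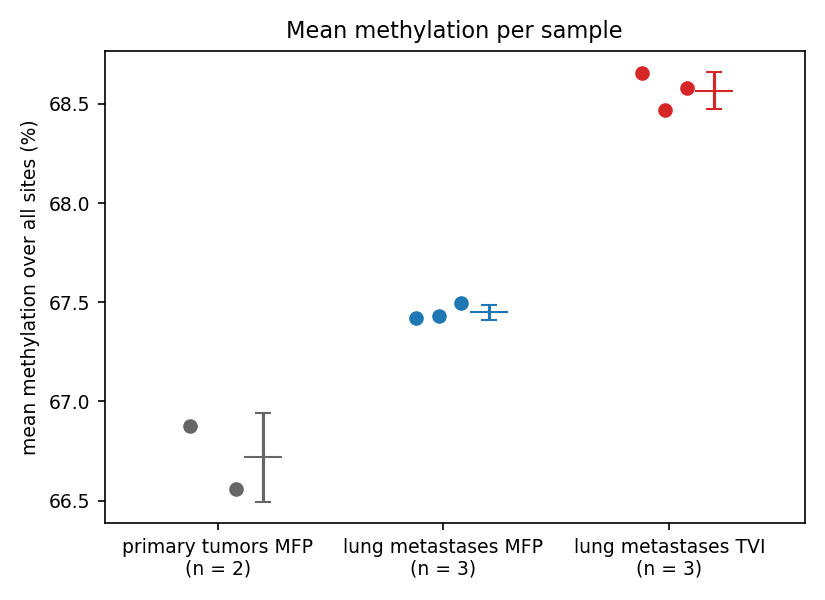
Mean methylation over 136069 sites (vertical axis, percent, not starting at 0) for each sample (points), with the group mean and SD (bars) in primary tumors MFP (n = 2), lung metastases MFP (n = 3) and lung metastases TVI (n = 3). Group means were 66.7%, 67.4% and 68.6%, and no sample of one group overlapped another group.

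The profiles of TVI metastases stood apart from the other samples. Across sites, which are not independent replicates, the correlation between samples was 0.992 between the tumors, 0.9899 to 0.9916 between tumors and MFP metastases, and 0.951 to 0.967 between TVI metastases and any MFP metastasis. Between TVI metastases it was 0.9922 to 0.9945. A principal component holding 90.3% of the variance of region means separated the 3 TVI metastases from the 5 other samples.

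The first comparison, all lung metastases against primary tumors, is the one named in the study's design. The region with the largest rise lay on chromosome 7 from 149618262 to 149618577 (10 sites). Its methylation was 26.8% ± 0.663 (SD, n = 2) in primary tumors, 41.2% ± 2.49 (SD, n = 3) in MFP metastases and 82.9% ± 5.61 (SD, n = 3) in TVI metastases, a rise of 35.2 points over both metastasis groups (SE 2.62, limma adjusted p = 9.61e-05). On chromosome 2 from 27629557 to 27631958, a region of 46 sites rose from 51.6% ± 1.26 in tumors to 60.2% ± 0.822 in MFP and 81.2% ± 1.29 in TVI metastases (adjusted p = 1.37e-05). A pair of adjacent regions on chromosome 12 rose together, by 17.0 points from 8781817 to 8784849 (40 sites) and by 17.3 points from 8785547 to 8790549 (56 sites). The largest fall among named regions lay on chromosome 15 from 97645518 to 97646332, where methylation was 49.0% ± 2.28 in tumors, 44.2% ± 1.16 in MFP and 26.7% ± 3.12 in TVI metastases (adjusted p = 0.000518).

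The other named rises lay on chromosome 14 from 56384689 (19.6 points), chromosome 11 from 117810330 (18.05 points), chromosome 17 from 27181077 (17.6 points), chromosome 11 from 49461954 (16.8 points), chromosome 6 from 86066664 (16.6 points) and chromosome 5 from 125663067 (15.99 points). Among the other falls, methylation fell by 12.6 points on chromosome 16 from 10784921, fell by 11.8 points on chromosome 8 from 97876962 and fell by 10.5 points on chromosome 12 from 113146598. On chromosome 7 from 85721511 it fell by 6.99 points, on chromosome 9 from 21530332 it fell by 5.81 points, and on chromosome 3 from 97846482 it fell by 5.47 points. On chromosome 8 from 123638488 it fell by 4.98 points, on chromosome 5 from 3344433 it fell by 4.41 points, and on chromosome 2 from 168589508 it fell by 4.36 points. All 20 of these regions also differed in the same direction between TVI and MFP metastases, whereas 5 of the 20 (4 rises and 1 fall) passed between MFP metastases and tumors.

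At single sites, 4 of the 10 largest rises lay inside the chromosome 2 region, led by position 27630109, at 24.2% ± 8.79 in tumors, 56.6% ± 5.47 in MFP metastases and 92.4% ± 5.53 in TVI metastases (adjusted p = 0.00108). On chromosome 11, position 68264653 rose from 5.85% ± 0.302 to 20.5% ± 3.63 and 77.2% ± 6.59. Of the 10 largest falls, 5 lay on chromosome 1 between 59537821 and 59541859. The largest, at position 59540305, had 76.5% ± 7.11 in tumors, 59.1% ± 9.09 in MFP and 2.99% ± 2.51 in TVI metastases.

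In total, 6954 sites were higher and 2208 lower in lung metastases, and so were 1284 and 147 of the 3083 regions. After quantile normalization the split was 3253 higher and 3427 lower for sites, and 533 and 386 for regions. Of the 9162 called sites, 7074 also differed between the metastasis groups, and 52 passed in the same direction between MFP metastases and tumors. Over the 9162 sites, the median difference from the tumors along the call was 4.29 points in MFP and 26.7 points in TVI metastases. No primary tumor was marked TVI, so lung site and label cannot be told apart in the TVI part of these calls. With the 6 metastases as 1 group, an alternative added after the data were examined, limma called 0 sites (10224 at an unadjusted p under 0.05) and 15 regions, and none of the 20 named regions passed. Without primary tumor replicate 1 or 2, the calls numbered 2279 and 2239 sites.

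MFP metastases were close to the MFP primary tumors and differed mainly by small rises. The chromosome 7 region from 149618262 was 14.3 points higher (SE 2.93, adjusted p = 0.0372). On chromosome 15 from 85388224 to 85389961 (16 sites), methylation was 69.6% ± 1.21 in tumors and 79.6% ± 1.07 in MFP metastases (adjusted p = 0.00176). On chromosome 2 from 27590556 to 27591172 (5 sites), it was 40.8% ± 0.504 and 53.6% ± 2.47 (adjusted p = 0.0106). The other named rises lay on chromosome 18 from 75538929 to 75539188, at 61.9% ± 4.74 and 72.8% ± 2.45 (adjusted p = 0.0477), and on chromosome 11 from 8597230 to 8597723, which was 9.48 points higher at 69.5% ± 0.956 in MFP metastases (adjusted p = 0.0241).

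The falls in MFP metastases were smaller than these rises. Methylation fell by 4.85 points on chromosome 4 from 3703109 to 3706045 (26 sites, adjusted p = 0.0161), and fell by 4.37 points on chromosome 9 from 20902308 to 20903126 (9 sites, adjusted p = 0.00973). It fell by 3.93 points on chromosome 16 from 94010837, fell by 3.51 points on chromosome 19 from 3339070 and fell by 2.34 points on chromosome 1 from 93842039. All 5 of these regions were higher in TVI metastases than in the same tumors, by 9.19 points on chromosome 4 and by 13.4 points on chromosome 9.

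Among single sites, position 173094583 on chromosome 2 had 14.7% ± 0.972 in tumors and 51.6% ± 6.48 in MFP metastases (adjusted p = 0.0420), and position 173082184 on the same chromosome had 21.3% ± 2.17 and 55.5% ± 2.16 (adjusted p = 0.0265). Position 78896867 on chromosome 11 was at 15.4% ± 1.54 in tumors, 49.3% ± 6.46 in MFP metastases and 10.5% ± 3.18 in TVI metastases. The other named rises were position 77635514 on chromosome 15 (36.5 points) and position 149626004 on chromosome 7 (35.9 points). The 5 sites that fell were position 168345235 on chromosome 2, which fell by 24.5 points, position 124956520 on chromosome 8, which fell by 24.3 points, position 136387507 on chromosome 5, which fell by 22.2 points, and positions 46530381 and 46530257 on chromosome 19, which fell by 18.3 points and fell by 13.3 points.

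In this comparison 58 sites were higher and 5 lower, and 152 regions were higher and 10 lower. Quantile normalization gave 21 and 7 sites, and 49 and 23 regions. Leaving out any 1 of the 8 samples left 0 to 18 sites (10620 to 11802 at an unadjusted p under 0.05 where limma called 0), so the calls at single sites depend on each sample. Region calls fell to 56 without primary tumor replicate 2, to 99, 87 and 59 without MFP metastasis replicates 1, 2 and 3, and to 87 without TVI metastasis replicate 3. Of the 10 named regions, the one on chromosome 15 from 85388224 passed in every alternative in which it was formed, and the other 9 each lost the call in at least 1.

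**Figure D2:**
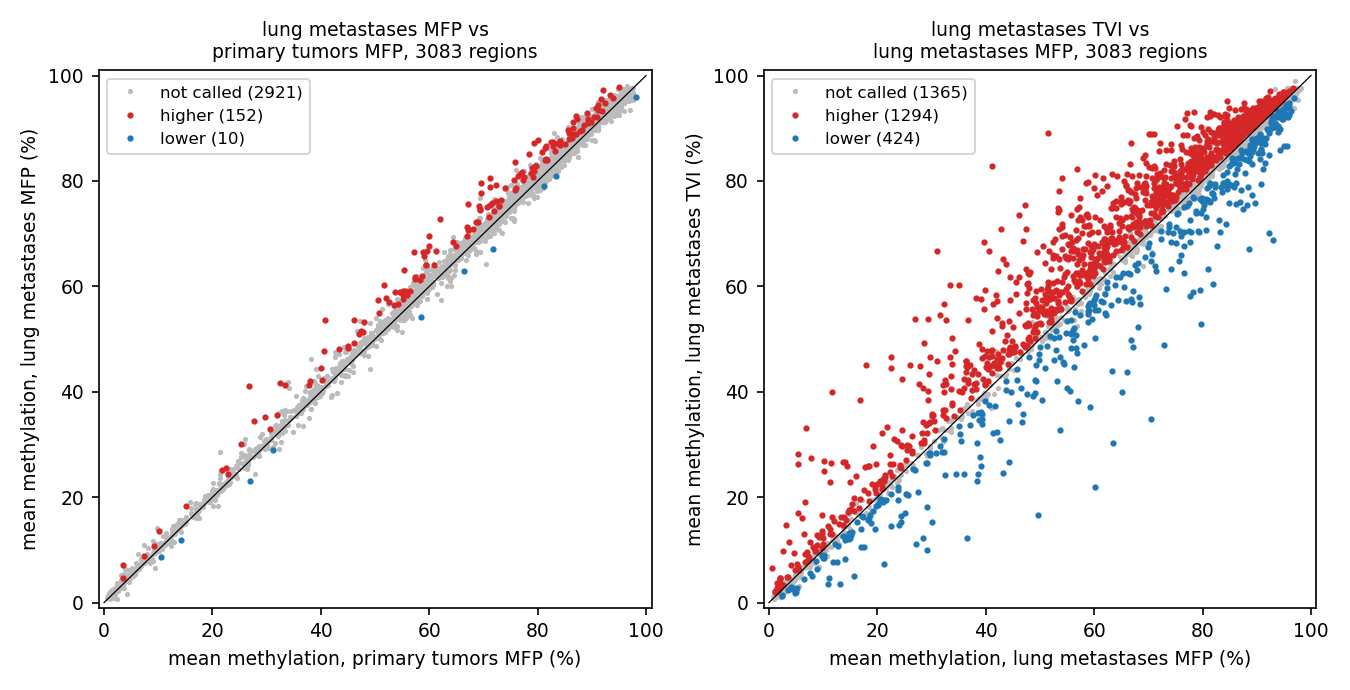
Mean methylation of 3083 regions (percent on both axes), MFP metastases against primary tumors on the left and TVI against MFP metastases on the right, with called regions in color and the line of equality. On the left 152 regions were called higher and 10 lower, and on the right 1294 and 424; with quantile normalization these were 49 and 23, and 928 and 687.

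TVI metastases differed from the primary tumors at many regions and in both directions. No tumor was marked TVI, so organ and label differ together in this comparison. The chromosome 7 region from 149618262 rose by 56.1 points (SE 2.93, adjusted p = 5.71e-06). On chromosome 15 from 85408652 to 85409299 (13 sites), methylation rose from 26.0% ± 2.94 (SD, n = 2) to 66.8% ± 3.62 (SD, n = 3), and on chromosome 2 from 152734667 to 152734975 (3 sites) from 55.0% ± 4.69 to 89.1% ± 2.19. Named rises on chromosome 14 from 56384689 and chromosome 11 from 117810330 reached 32.6 and 32.2 points. The largest fall lay on chromosome 12 from 56591181 to 56592653 (34 sites), where methylation was 58.7% ± 0.986 in tumors and 21.9% ± 4.93 in TVI metastases (adjusted p = 1.40e-05).

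Further falls in TVI metastases lay on chromosome 11 from 53584238 to 53585380 (68.6% ± 0.0416 in tumors and 34.7% ± 4.45 in TVI metastases), on chromosome 15 from 77667560 to 77668748 (58.8% ± 1.37 and 30.2% ± 6.03) and on chromosome 19 from 9017895 to 9018240 (80.7% ± 0.144 and 52.9% ± 2.88). The region with most sites among those named, on chromosome 1 from 59537821 to 59541859 (192 sites), fell from 49.1% ± 0.188 to 16.7% ± 3.27 (adjusted p = 5.07e-06). It held all 5 of the named site falls, led by position 59540430, at 97.0% ± 1.36 in tumors and 11.8% ± 6.31 in TVI metastases. The largest site rise was at position 49462142 on chromosome 11, 76.9 points above 3.06% ± 1.22 in tumors (adjusted p = 3.41e-06), followed by position 141083023 on chromosome 5 (76.8 points) and position 8818150 on chromosome 12 (76.2 points). Position 141083017 on chromosome 5 rose by 74.8 points and position 95936406 on chromosome 1 by 74.5 points.

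Against the tumors, 15428 sites were higher and 7124 lower in TVI metastases, and 1530 regions were higher and 298 lower. Quantile normalization gave 10073 and 9688 sites, and 861 and 663 regions, with 17194 of the 22552 site calls retained in the same direction. Of the sites called against the tumors, 40 were higher and 3 lower in both metastasis groups, where independent lists would share 6.58 and 0.262. For regions, 130 were higher and 2 lower in both, against 75.4 and 0.967. Both comparisons use the same 2 tumors, and 20 simulations of unchanged groups against them made at most 1 site call per comparison, too few to set a chance level for shared calls. The differences of the metastasis groups from the tumors correlated across sites at 0.217, against 0.5999 simulated with no effect, and their covariance was 8.40 squared points, against 4.46 simulated and 5.79 from the difference between the tumors. Across regions the correlation was 0.244, against 0.610 simulated. The covariance there was 2.13 squared points, against 0.393 simulated and 0.538 from the difference between the tumors. The simulated correlations were set by the group sizes, and the wide TVI differences lowered the observed ones. The lower observed correlations therefore do not mean that fewer changes were shared. With only 2 tumors they could not be divided, so part of the excess covariance may come from the shared tumors.

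The last comparison set TVI against MFP metastases, both from the lung. The chromosome 1 region from 59537821 to 59541859 was at 49.6% ± 1.01 (SD, n = 3) in MFP metastases and 16.7% ± 3.27 (SD, n = 3) in TVI metastases (adjusted p = 3.10e-06), and all 112 of its called sites were lower in TVI metastases. The chromosome 12 region from 56591181 fell from 60.2% ± 0.996 to 21.9% ± 4.93 and the chromosome 11 region from 53584238 from 70.4% ± 0.900 to 34.7% ± 4.45. Methylation fell by 33.2 points on chromosome 15 from 77667560 and fell by 26.8 points on chromosome 19 from 9017895. MFP metastases and primary tumors were within 4.66 points of each other in these 5 regions, and none of the 5 passed between them.

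Rises in TVI over MFP metastases were led by the chromosome 7 region from 149618262 (41.7 points, adjusted p = 1.03e-05). The chromosome 2 region from 152734667 rose by 37.7 points and the chromosome 15 region from 85408652 by 35.8 points. On chromosome 5 from 139569504 to 139570137 (9 sites), methylation was 39.7% ± 0.699 in MFP and 68.4% ± 1.27 in TVI metastases (adjusted p = 1.48e-06), and on chromosome 11 from 49461954 to 49462261 (4 sites) it rose by 28.3 points from 11.6% ± 1.01. The largest site rises were at positions 141083023 (81.9 points), 145664902 (81.1 points) and 141083017 (79.7 points) on chromosome 5, at position 80400051 on chromosome 10 (80.3 points) and at position 8818150 on chromosome 12 (79.0 points). The 5 largest site falls all lay in the chromosome 1 region, led by position 59540732, at 96.1% ± 3.62 in MFP and 8.51% ± 3.12 in TVI metastases (adjusted p = 8.02e-07).

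**Figure D3:**
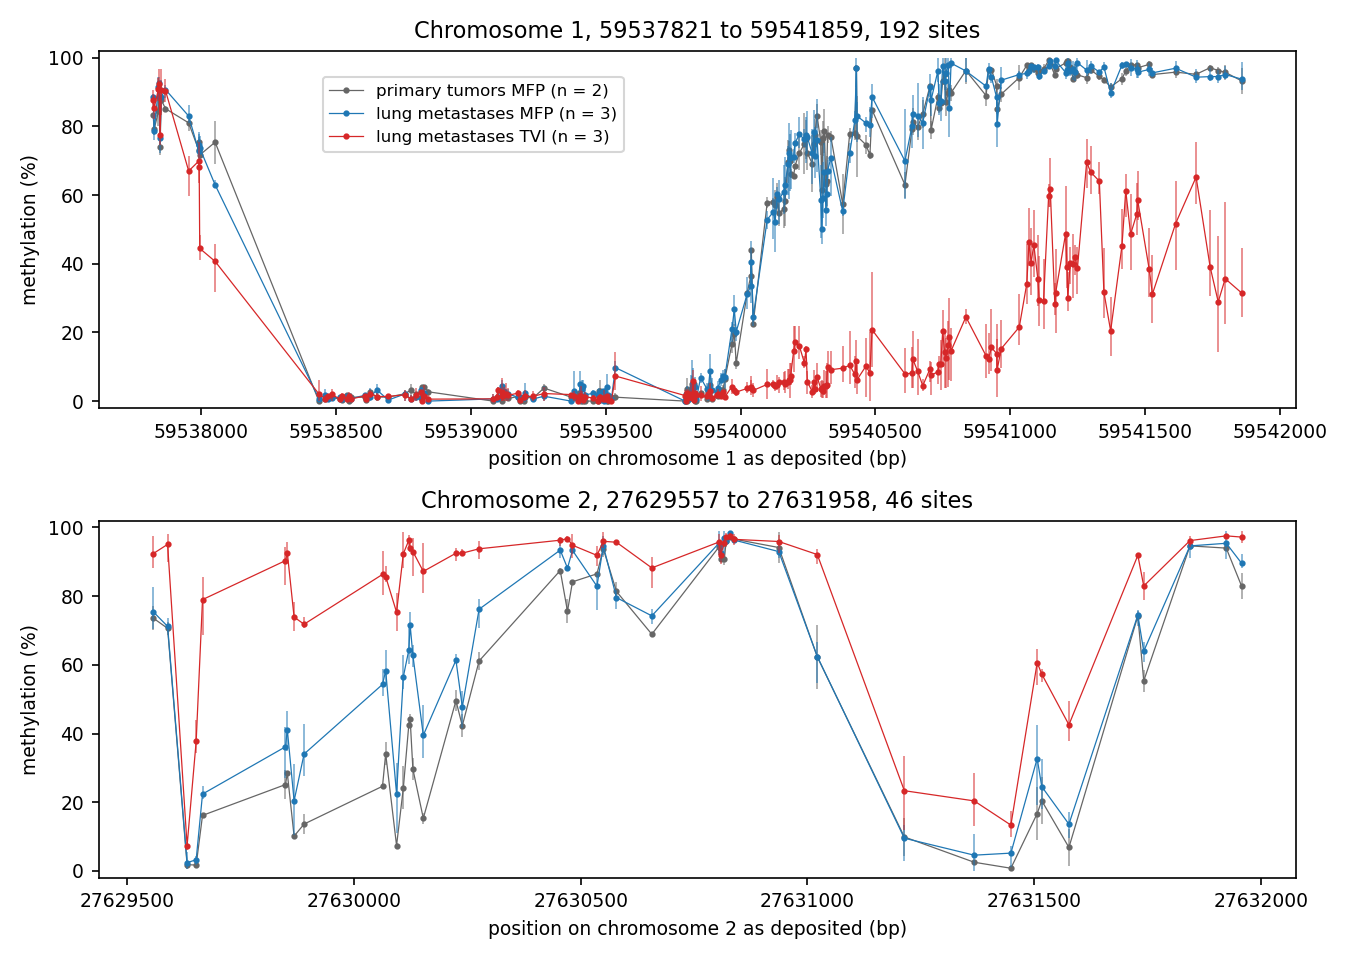
Methylation (vertical axis, percent) along a chromosome 1 region of 192 sites and a chromosome 2 region of 46 sites (horizontal axis, position in bp as deposited), with points for group means and vertical lines for the range of samples. In the chromosome 1 region TVI metastases averaged 16.7% against 49.6% in MFP metastases, and in the chromosome 2 region 81.2% against 60.2%.

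Between the metastasis groups, 14120 sites were higher and 8881 lower in TVI metastases, with 351 rises and 368 falls of at least 50 points. Of these sites, 29 went from at most 20% in MFP metastases to at least 80% in TVI metastases, and 54 went from at least 80% to at most 20%. Among regions, 1294 were higher and 424 lower, and called sites of both directions occurred within 1370 of the 3083 regions. Quantile normalization gave 11542 higher and 11017 lower sites, and 928 and 687 regions, with 20411 of the 23001 site calls retained in the same direction.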

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

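The site comparisons and their quantile normalization were planned before the data were examined, while the region comparisons, the splits, the test for other cells and the bounds used to weigh explanations were chosen after the differences between the groups had been seen. The difference from the primary tumors was not the same in both metastasis groups at 23001 sites and 1718 regions, by limma's test of TVI against MFP metastases, which is the test of that difference. At 7 sites and 14 regions both metastasis groups passed against the primary tumors in opposite directions. These include the chromosome 18 region from 75538929 to 75539188, which was 10.9 points above the tumors in MFP metastases (limma adjusted p = 0.0477) and lay at 49.0% ± 2.88 (SD, n = 3) in TVI metastases, against 61.9% ± 4.74 (SD, n = 2) in the tumors. They also include the chromosome 9 region from 20902308 to 20903126, at 58.5% in tumors, 54.1% in MFP metastases and 71.8% in TVI metastases. For MFP metastases against tumors, neither region kept its call in every alternative.

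For the wide difference between TVI and MFP metastases, chance, a common shift and other cells were weighed. Of the 10 splits of the 6 metastases into 3 and 3, 1 (the real one) gave as many calls, 23411 sites and 1742 regions, with 0 in the highest other split, but 10 splits are too few for a share under 0.05. A shift common to all sites of a sample is argued against by the 88.7% of site calls that passed in the same direction after quantile normalization. Cells of another kind below 50% of each sample, which move a level by at most 50 points, are argued against only at the 272 called sites that differed by more than 60 points (264 of them more than 2 SE above 50). Such cells at the other called sites (median over all calls 17.8 points), a larger share of them and the biological difference behind the MFP and TVI labels stay open and untested.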

How the results depend on the processing

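The alternatives for sites and for mean methylation were planned before the data were examined, while those for regions and the model with metastases as 1 group were chosen after. Site calls for all metastases against tumors numbered 9162, and 5631 on the log2 odds scale, 5200 with the replicate block, 0 with metastases as 1 group (10224 at an unadjusted p under 0.05; the difference between metastasis groups then counts as spread) and 2239 to 9637 with each sample left out. For MFP metastases against tumors, 63 sites became 3 (log2 odds), 28 (quantile normalization), 155 (no variance trend), 117 (robust variance), 455 (range of at least 10 points), 0 with the replicate block or only the samples compared (10913 and 10382 unadjusted), and 0 to 18 with each sample left out. The TVI counts stayed within 1.5 times for sites under every alternative run, at 16491 to 22671 against tumors and 18497 to 22904 against MFP metastases with each sample left out.

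For regions, a difference of at least 10 points left 81 (all metastases), 4 (MFP against tumors), 291 (TVI against tumors) and 269 (TVI against MFP). Gaps of 200 bp gave 2705, 3983 and 3800, and gaps of 1000 bp gave 875, 1040 and 995, for all metastases, TVI against tumors and TVI against MFP, where regions become more and fewer by construction. All metastases had 919 regions with quantile normalization and 15 as 1 group. MFP against tumors, with 162 regions, had 72 with quantile normalization, 65 with the replicate block and 87 with only the samples compared. With each sample left out the region counts were 971 to 1391, 56 to 171, 1535 to 1831 and 1503 to 1742 in the order given first. Except where the construction is stated, the cause was not tested.

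Deviations of samples with the same number correlated at -0.0037 to 0.0172, and of samples with different numbers at -0.0172 to 0.0073. Both tumors correlated best with their own number in each metastasis group, while MFP metastasis replicates 1 and 2 did not among TVI metastases. With only 2 tumors, whose deviations mirror each other, these values cannot settle whether the numbers pair samples. The block therefore stands for a shared number only. None of the named sites and regions reversed. For TVI against tumors and against MFP metastases, named items were retained in every alternative in which they were formed. For MFP against tumors, the call was lost in 110 of 160 site and 70 of 171 region alternatives. For all metastases it was lost in 25 of 320 site and 28 of 348 region alternatives. Differences in mean methylation kept their sign, from 0.573 to 0.888 points for MFP and 1.69 to 2.01 for TVI against tumors. With tumors reduced to 1 sample, that sample was assumed to vary like the other groups. Alternatives for missing values (none were missing), promoters, gene lists and genomic context were not run, and no coverage minimum could be set.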

Other observations

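Apart from the count without TVI replicate 1, which was planned, the tests in this part were chosen after the results were seen, and the class limits and bounds were set after an exploratory look at the values. The direction of the mean difference between metastasis groups followed the local density of sites. No version was run without the chromosome 1 region (192 sites, 112 called lower), so its weight in the dense classes is unknown. Sites with 0 to 3 others within 250 bp had a mean of 73.6% ± 0.0286 (SD, n = 3) in MFP metastases and 76.1% ± 0.0646 (SD, n = 3) in TVI metastases. Sites with over 30 others had 24.9% ± 0.0665 and 23.1% ± 0.216. The TVI minus MFP difference was 2.51, 2.03, 0.921, -0.823 and -1.81 points over the 5 classes from sparse to dense, each with an exact permutation p of 0.1, the smallest possible, and an adjusted p of 0.2 over 10 tests. After quantile normalization the middle class turned negative and the others kept their sign, at 1.12, 0.728, -0.136, -1.60 and -2.40 points. That step gives all samples the same mean over all sites. The classes therefore had to balance around 0, while their order was not set. The MFP metastases were 0.833, 0.878, 0.726, 0.452 and 0.207 points above the tumors in the same classes (exact p = 0.2, the smallest possible). After quantile normalization they were -0.143 to 0.0302 points from the tumors, again balanced around 0 by construction.

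Sites with intermediate levels in the primary tumors were called most often between TVI and MFP metastases. The tumors took no part in the contrast, but they entered its estimate of the spread and lay close to the MFP metastases. Of sites at 20% to 40% in the tumors, 63.0% were called, with 2433 higher and 1081 lower in TVI metastases. Of those at 80% to 100%, 7.57% were called, with 1910 higher and 4360 lower, and of those at 0% to 20%, 16.3% were called, with 4149 higher and 911 lower. Fractions are bounded, so the direction in those outer classes was largely set by the class limits, which may also have limited the number of calls. In the classes from 40% to 60% and from 60% to 80%, 2347 and 3281 sites were higher and 1067 and 1462 lower. After quantile normalization the middle classes had 1972, 1843 and 2716 higher and 1411, 1382 and 1899 lower sites, from low to high. From MFP to TVI metastases, 5296 sites left the range from 35% to 65% and 5007 entered it. The TVI minus MFP differences of neighboring sites correlated across sites at 0.649 at up to 50 bp and 0.116 at over 500 bp. For MFP metastases minus tumors, where 63 sites were called, the values were 0.3775 and 0.0169, so part of the short-range correlation was present with few calls. The share of sites called ranged from 10.2% on chromosome 18 to 20.5% on chromosome 12, where 73.4% of the called sites were higher in TVI metastases.

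TVI metastasis replicate 1 showed smaller differences from the MFP metastases than the others. At sites where replicate 3 gained at least 30 points it showed 82.6% (SE 1.19) of the change of replicate 2, and at sites where replicate 3 lost as much it showed 78.5% (SE 0.926), by a jackknife over chromosomes. At sites picked in the same way by replicate 2, it showed 87.1% (SE 0.660) and 83.5% (SE 0.796) of the change of replicate 3. A mixture with cells of the MFP metastasis profile in 1 fixed share may be present. It would give equal percentages at gained and lost sites if replicate 1 otherwise matched the replicate it is compared with. The gaps of 4.14 points (against replicate 2) and 3.54 points (against replicate 3) cannot be judged. The only pair without replicate 1 (2 against 3) also had unequal percentages, 104.82% and 106.42%. Cells of a profile unlike all other samples may be present, and could not be judged from the 216 sites where replicate 1 lay over 10 points outside the 7 other samples (937 for TVI replicate 2 and 638 for primary tumor replicate 2), because no profile of such cells is held here. A TVI metastasis that had changed less far also stays open, and without replicate 1 the TVI against MFP comparison called 21262 sites.

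The rise of MFP metastases over the primary tumors may be in part a shift common to all sites. After quantile normalization 59 of the 162 called regions (36.4%) passed in the same direction, too few to argue against such a shift and too many to take it as the whole cause by the bounds set afterwards. Over all 162 the median difference along the call went from 3.57 points (quartiles 2.51 and 4.83) to 2.74 points (1.80 and 3.87), but regions picked for their call have inflated differences. In the 103 regions whose call ended, the median went from 3.16 points (2.32 and 4.03) to 2.12 points (1.38 and 2.88), smaller in all 103. Their median SE was 0.567 and 0.571 points, so smaller differences followed from picking regions that lost the call. In the 59 regions that kept the call, the median went from 4.66 to 3.85 points, smaller in 49. Quantile normalization removes a net gain whatever its cause, so these decreases do not argue for a common shift. A common shift stays open. So do cells of another kind in the samples and the biological difference between tumor and lung metastasis, neither of which was tested for this comparison.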
